A study of Mus musculus with 7 samples.

How the data were processed

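RNA was taken from whole mouse femurs crushed in Trizol and purified on columns, and libraries were made with a stranded mRNA kit, per the labels' protocols. The groups were uninjured controls (3 libraries) and mice 3 days after a controlled cortical impact (4 libraries). The authors deposited a table of raw read counts per Ensembl gene (49671 genes, whole numbers) and a table of normalized values for 18549 genes. STAR, DESeq and the GRCm38 mouse genome are named in the submitters' processing notes, without versions. The counting step, its use of strand and its treatment of reads that match several genes are not given in the sources used here, so genes with near-identical copies or overlapping neighbours are uncertain.

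The deposited normalized table holds values on a log2-like scale, judged from the values themselves, with a floor of 4.21 where the count is 0; how the authors made it is not given in the sources used here beyond the tools named. For the 4274 genes with a mean of at least 1000 counts, these log2 values lay within 0.175 of the log2 of the count scaled by size factors computed here (median absolute difference 0.0288). Every gene in that table had counts in at least 3 libraries. All tests used the deposited counts, and the log2 table served only for this check. Total counts were 20675655, 15461528 and 19442998 in controls 1 to 3 and 21339407, 21730054, 20470241 and 21783534 in TBI 1 to 4. Libraries of a group differed by more than sampling noise: the chi-square of their counts per degree of freedom was 27.2 or more in each pair, over genes with at least 20 counts.

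Gene symbols and coordinates came from GENCODE release M21 on GRCm38, which matched 49326 of the 49671 identifiers (99.3%). Counts were filtered with filterByExpr, which left 17144 genes, and scaled by TMM. The main test was edgeR's quasi-likelihood F-test (glmQLFit and glmQLFTest at their defaults, edgeR 4.0.16 in R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are TBI minus control on the log2 scale, with the standard error taken from the estimate and its F statistic. CPM values use TMM-scaled library sizes. DESeq2 1.42.0 was an alternative, and it gave no adjusted p for 1664 genes.

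Before the data were examined, 40 gene lists of skeletal, marrow, blood, vessel, nerve, muscle and fat cells and of response pathways were fixed, and each had at least 5 tested members. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and beside it with an estimated correlation and with fry, each adjusted over the 40 lists. The rule for named genes was also fixed then. It took (a) up to 12 genes per direction past the threshold with separated groups, (b) the 3 members with the smallest p of each called list, (c) a set of 14 bone, marrow and muscle genes given as values whatever their test, and (d) the 5 genes with the smallest p per direction where fewer than 5 passed. Predicted genes and antigen receptor segments were not named. Part (a) named no gene. Genes outside the rule are said to have been chosen after their values were seen.

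The procedure was tested on simulated counts drawn from the real means and library sizes, with a set of genes changed by known folds among 16756 tested. With 3 control and 4 TBI libraries, edgeR recovered 0 of 67 genes changed 1.5-fold, 25 of 67 changed 2-fold (37.3%) and 62 of 66 changed 4-fold (93.9%), with 11 false calls. DESeq2 recovered 3 of 67, 47 of 67 (70.1%) and 64 of 66 (97.0%), with 45 false calls.

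Alternatives fixed beforehand were other scalings (RLE, upper quartile), no filter and a filter of 1 CPM in 3 libraries, DESeq2, limma-voom with and without quality weights, the replicate number as a block, the muscle or erythroid list mean as a covariate, a minimum fold of 1.5, a threshold of 0.1, and each library left out in turn. Single values were compared by two-sided exact permutation of the 35 splits of 7 libraries into 3 and 4. No batch is named in the labels.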

Results

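Messenger RNA was sequenced from the femurs of wild-type mice 3 days after a traumatic brain injury (TBI) and from uninjured mice. The injury was a controlled cortical impact, in which a piston strikes the exposed brain surface under controlled conditions. The whole bone was crushed for RNA, so each library holds transcripts of bone, cartilage, marrow and any tissue left attached. There were 3 control and 4 TBI libraries, with total counts of 15461528 to 21783534 and 22360 to 23424 genes detected per library. At these depths, before TMM scaling, 1 count equals 0.0459 to 0.0647 CPM (counts per library, scaled to a common depth). A count of 0 then allows up to 0.138 to 0.194 CPM, a bound that covers counting error only. The labels number the replicates but do not say that each came from a different mouse, so p-values measure the spread between these samples. Xist had 15997 to 25139 counts in each library, and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had 0 counts in all 7. The comparison asks how gene expression in a distant bone differs after an injury to the brain. The treatment label of the other group reads only control. Unless those mice had the same surgery, an effect of exposing the brain cannot be told apart from that of the impact.

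The mRNAs of bone, cartilage and tendon cells were lower in the femurs of the injured mice. Of the 84 tested genes on 5 lists of skeletal genes, 83 had a lower estimate after TBI, with a median log2 fold change of −0.66 (quartiles −0.76 and −0.52). For 53 of the 84, every TBI library lay below every control library. These 5 lists were grouped after they were seen to be lower, so these counts describe them and are not a test. The osteoclast list (median −0.27) and the marrow stromal list (median 0.02) are not among them. Col9a2, a chain of the collagen IX that coats cartilage fibrils, measured 195.9 ± 1.86 CPM (SD, n = 3) in controls and 105.3 ± 14.1 CPM (SD, n = 4) after TBI. No gene passed the threshold over all genes tested in edgeR's quasi-likelihood test, so the lists carry the comparison and genes are given as values. In the lists called by camera, the estimated correlation between members ran from 0.0327 (BMP pathway) to 0.979 (neutrophil precursor), against the preset 0.01. The p-values with the preset correlation are therefore too small, and counts of members that moved are not counts of independent observations.

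The chondrocyte and growth plate list fell by the equivalent of 1.58-fold at its median (log2 fold change −0.66, 18 of 18 members lower). Its test in limma's camera gave an adjusted p of 1.54e-24 with the preset correlation, and it was the only list that also held with an estimated correlation (adjusted p = 0.049 with an estimated correlation) and in the directional fry test (adjusted p = 0.0109). Adjusted over the list alone, 15 of its 18 members passed in edgeR, against 0 adjusted over all genes tested (7 in DESeq2). The list mean was 6.72 ± 0.0377 log2 CPM in controls (SD, n = 3) and 6.03 ± 0.115 after TBI (SD, n = 4). Col9a2 (ENSMUSG00000028626, protein coding, GRCm38 chromosome 4, 121039385 to 121055322, plus strand) had a log2 fold change of −0.90 ± 0.13 (SE). Its partner chain Col9a3 stood at −0.66 ± 0.13, and Acan, the large aggregating proteoglycan of cartilage, at −0.66 ± 0.15, from 298.9 ± 2.87 CPM in controls to 188.5 ± 30.8 after TBI.

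The osteoblast list fell, with a median log2 fold change of −0.67 and 19 of 20 members lower (camera adjusted p = 1.36e-24). That call was lost when the correlation between members was estimated (adjusted p = 0.153 with an estimated correlation). Adjusted over the list alone, 18 of the 20 members passed in edgeR, all of them lower, against 0 adjusted over all genes tested (8 in DESeq2). Alpl, the alkaline phosphatase that mineralizing cells carry (ENSMUSG00000028766, chromosome 4, 137741733 to 137796384, minus strand), had a log2 fold change of −0.67 ± 0.14 (SE) and went from 280.7 ± 43.4 CPM (SD, n = 3) to 177 ± 7.24 CPM (SD, n = 4). Sp7, a transcription factor required for osteoblast formation, stood at −0.79 ± 0.17, and Pth1r, the parathyroid hormone receptor, at −0.72 ± 0.15. Col1a1, the main collagen chain of bone, was at −0.72 ± 0.28, and Bglap, which encodes osteocalcin, at −0.97 ± 0.22. Bglap and its near-identical neighbour Bglap2 can share reads, so the split between them is uncertain. Together Col1a1 and Col1a2 took 2.14% ± 0.614 of counts in controls (SD, n = 3) and 1.21% ± 0.274 after TBI (SD, n = 4). A two-sided exact permutation test gave p = 0.114, where the smallest p that 3 against 4 libraries allow is 0.0571.

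The fibrillar matrix and collagen processing list fell with all 26 members lower, at a median log2 fold change of −0.60 (camera adjusted p = 7.36e-32; adjusted p = 0.153 with an estimated correlation). Adjusted over the list alone, 24 of 26 members passed in edgeR, against 0 adjusted over all genes tested (9 in DESeq2). Loxl2, a lysyl oxidase relative that crosslinks collagen, had a log2 fold change of −0.80 ± 0.16 (SE), Lum, a small proteoglycan of collagen fibrils, −0.68 ± 0.14, and Col5a2 −0.75 ± 0.17. The tendon and ligament list fell by a similar amount, with 8 of 8 members lower at a median of −0.72 (camera adjusted p = 1.32e-10; adjusted p = 0.251 with an estimated correlation), and 7 of the 8 passed when adjusted over the list alone. Fmod was at −0.72 ± 0.18, Tnmd at −0.73 ± 0.19 and Thbs2 at −0.80 ± 0.21. Without control 2, the Thbs2 value was −0.53.

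Osteocyte genes, made by the cells embedded in mineralized bone, fell with 12 of 12 members lower and a median log2 fold change of −0.64 (camera adjusted p = 9.66e-12; adjusted p = 0.153 with an estimated correlation). Adjusted over the list alone, 6 of the 12 passed in edgeR, among them Ptprz1 (−0.86 ± 0.16), Gja1 (−0.62 ± 0.15), the main gap junction protein of bone cells, and Phex (−0.85 ± 0.22). Sost, which encodes the Wnt inhibitor sclerostin, was at −1.11 ± 0.58 with overlapping groups (7.67 ± 2.81 CPM in controls, n = 3, and 3.50 ± 3.03 after TBI, n = 4), and at −1.9 without TBI 2. Dmp1 was at −0.41 ± 0.34, and at −0.24 without control 1, −0.64 without control 3, −0.74 without TBI 1 and −0.22 without TBI 4. With the erythroid list mean as a covariate, Dmp1 turned to 0.26. Wnt pathway targets fell at a median of −0.36 with 10 of 12 members lower (camera adjusted p = 1.94e-04; adjusted p = 0.153 with an estimated correlation), and 0 members passed in edgeR when adjusted over the list alone (4 at an unadjusted p under 0.05, 0 in DESeq2). Dkk1, a secreted Wnt inhibitor that stands on this list and the osteocyte list, was at −1.22 ± 0.34, Wif1 at −0.57 ± 0.17 and Nkd2 at −0.48 ± 0.17. The BMP pathway list was called lower (camera adjusted p = 0.00885; adjusted p = 0.31 with an estimated correlation) although its median was −0.12. Each library left out moved that median by over 1.5 times, and it lay between −0.34 without control 1 and −0.0342 without TBI 4: it was −0.21 without control 2, −0.20 without control 3, −0.23 without TBI 1, −0.17 without TBI 2 and −0.20 without TBI 3. Without TBI 3 and TBI 4 together, chosen after seeing the data, the BMP call ended (adjusted p = 0.212), as it did with the erythroid list mean as a covariate (−0.25, adjusted p = 0.0635). Id3, a target of BMP signalling, was its only member past the threshold when adjusted over the list alone (−0.49 ± 0.11), with Bmp7 at −0.93 ± 0.35 (−0.57 without control 2) and Bambi at −0.49 ± 0.17.

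**Figure D1:**
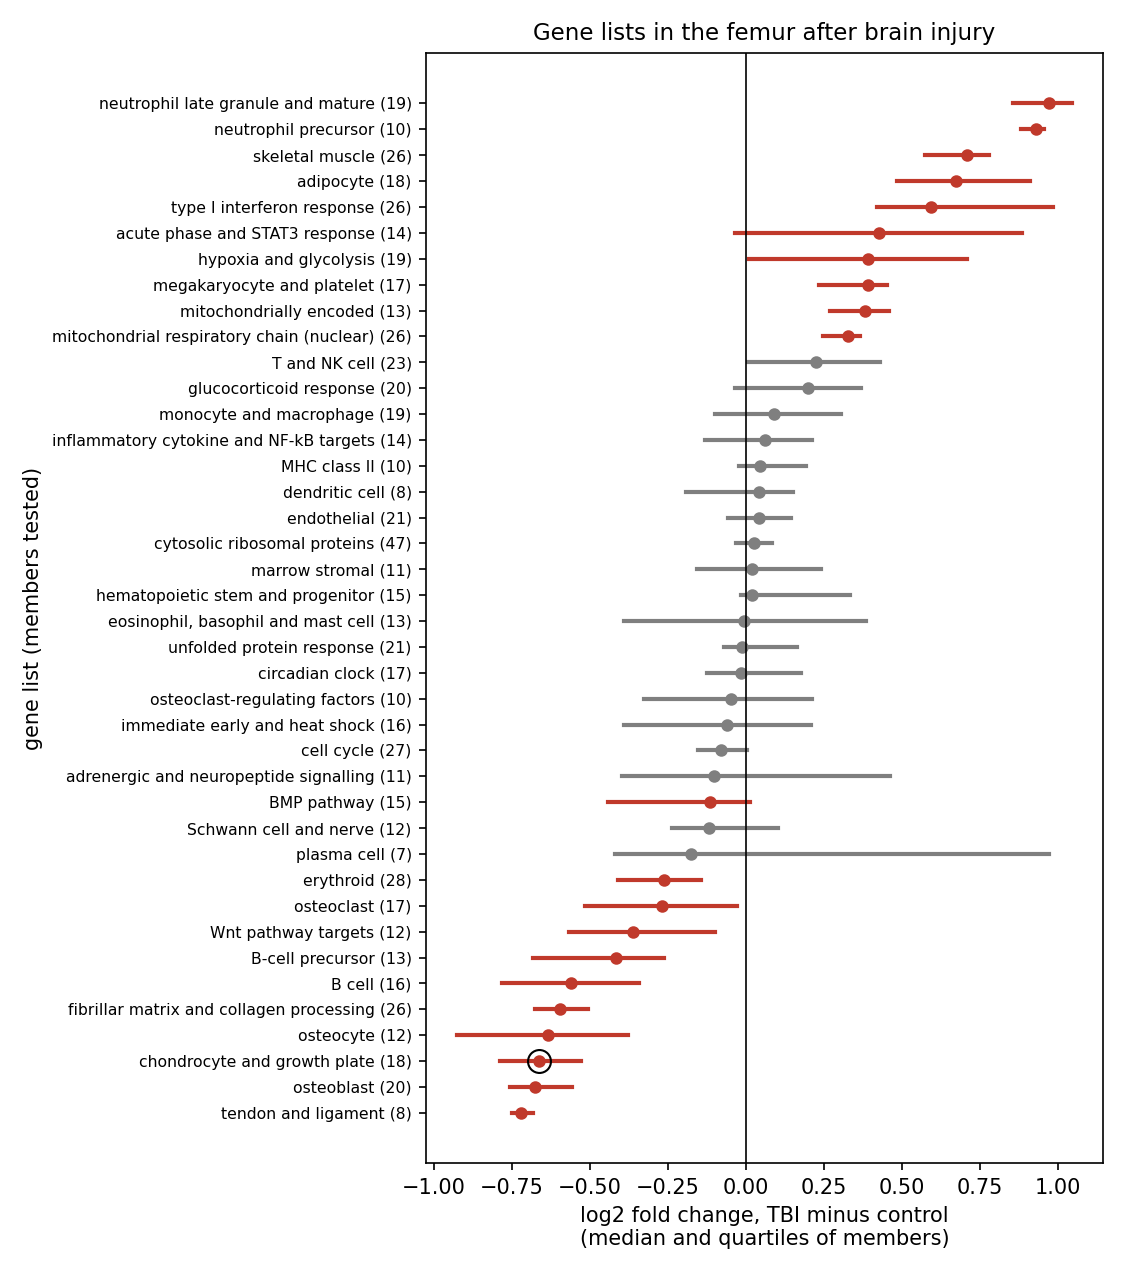
Median log2 fold change (TBI minus control, horizontal axis) of the tested members of 40 gene lists, with lines from the lower to the upper quartile; red marks lists past an adjusted p of 0.05 in camera with the preset correlation, grey the others, and the black ring the list that also passed with an estimated correlation. The 5 skeletal lists lie between −0.72 and −0.60, and the late neutrophil list lies highest at 0.97.

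Genes of bone-resorbing osteoclasts were also lower, with a median nearer 0 than those of the bone-forming lists, a difference that was not tested. The osteoclast list fell at a median log2 fold change of −0.27 with 13 of 17 members lower (camera adjusted p = 2.82e-04; adjusted p = 0.653 with an estimated correlation), and 0 members passed in edgeR when adjusted over the list alone (5 at an unadjusted p under 0.05, 0 in DESeq2). Ctsk, the collagen-degrading protease of osteoclasts, was at −0.74 ± 0.24 (SE), Acp5 at −0.54 ± 0.23, Siglec15 at −1.07 ± 0.32 and Atp6v0d2 at −0.51 ± 0.21. The call ended without control 1 (adjusted p = 0.0949) and without TBI 3 and TBI 4 together (median −0.20, adjusted p = 0.403, a setting chosen after seeing the data). It also ended with the muscle list mean as a covariate (−0.16, adjusted p = 0.115) and with the erythroid list mean as one (0.011, adjusted p = 0.549). The median was −0.41 without control 3, −0.51 without TBI 1 and −0.15 without TBI 4. The osteoclast-regulating factors were not called (median −0.05, camera adjusted p = 0.443): Tnfsf11, which encodes RANKL, was at −0.33 ± 0.26, and its decoy receptor Tnfrsf11b at −0.71 ± 0.25. The Tnfsf11 value was −0.16 without control 2, −0.52 without TBI 1 and −0.22 without TBI 2.

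Globin mRNAs were lower in every TBI library than in every control, while the mean of the B-cell list lay well below the controls in TBI 3 and that of the precursor list in TBI 2 and TBI 3. The erythroid list fell with 26 of 28 members lower and a median log2 fold change of −0.26 (camera adjusted p = 2.73e-09; adjusted p = 0.614 with an estimated correlation), and its median was −0.11 without control 1. The alpha-globin gene Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298, plus strand) had a log2 fold change of −0.93 ± 0.22 (SE), the beta-globin genes Hbb-bt and Hbb-bs −0.88 ± 0.22 and −0.77 ± 0.27, and Alas2, the erythroid form of the enzyme that starts heme synthesis, −0.67 ± 0.20. Adjusted over the list alone, Hba-a2 and Hbb-bt passed in edgeR, against 0 members adjusted over all genes tested (5 in DESeq2). Hba-a1 and Hba-a2, and likewise Hbb-bs and Hbb-bt, are near-identical copies whose reads may have been split between them. As a sum, the 4 globin genes took 4.23% ± 0.447 of counts in controls (SD, n = 3) and 2.35% ± 0.569 after TBI (SD, n = 4). Every TBI library lay below every control (exact permutation p = 0.0571, the smallest possible here). The B-cell list mean was 4.42, 3.80 and 4.20 log2 CPM in controls 1 to 3 and 4.29, 3.90, 2.13 and 3.67 in TBI 1 to 4. The list fell at a median of −0.56 with 14 of 16 members lower (camera adjusted p = 8.36e-05; adjusted p = 0.653 with an estimated correlation), and its median was −0.35 without control 1 and −0.23 without TBI 3. Without TBI 3 and TBI 4 together, chosen after seeing the data, the B-cell call ended (median −0.17, adjusted p = 0.67), as it did with the erythroid list mean as a covariate (−0.34, adjusted p = 0.107). Blk was at −0.77 ± 0.39 (−0.44 without control 1), Fcmr at −0.87 ± 0.40 and Spib at −0.82 ± 0.44 (−0.53 without TBI 3). Ighm, the heavy chain of IgM, was at 1.08 ± 0.61 on that list, with 1587 CPM in TBI 1 and 649.4, 272.7 and 261.1 CPM in TBI 2 to 4 against 265.6 to 380.9 in controls; it was singled out after its values were seen. The B-cell precursor list mean was 3.89, 3.19 and 3.40 log2 CPM in controls 1 to 3 and 3.46, 2.59, 2.06 and 3.47 in TBI 1 to 4. This list fell at −0.42 with 12 of 13 members lower (camera adjusted p = 9.21e-05; adjusted p = 0.653 with an estimated correlation). Its call ended without control 1 (−0.25, adjusted p = 0.0536) and with the erythroid covariate (−0.33, adjusted p = 0.0587), and the median was −0.74 without TBI 1, −0.24 without TBI 3 and −0.69 without TBI 4. Rag1, part of the recombinase that assembles antigen receptor genes, was at −1.14 ± 0.55, Vpreb3 at −1.05 ± 0.53, Pax5 at −0.68 ± 0.35 and Cd79a at −0.77 ± 0.47. Without TBI 3, Pax5 was at −0.43 and Cd79a at −0.45. In edgeR 0 members of either B-cell list passed when adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 called 0.

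Neutrophil mRNAs were higher in 3 of the 4 TBI libraries. The late granule and mature neutrophil list rose at a median log2 fold change of 0.97 with 18 of 19 members higher (camera adjusted p = 4.07e-07; adjusted p = 0.653 with an estimated correlation), and its median was 0.59 without TBI 1. The precursor list rose at 0.93 with 10 of 10 members higher (camera adjusted p = 5.71e-06; adjusted p = 0.614 with an estimated correlation). With the late list mean as a covariate, chosen after seeing the data, the precursor median was 0.11 (adjusted p = 0.256). The late list mean was 7.5, 6.86 and 6.89 log2 CPM in controls 1 to 3, and 8.78, 8.06, 6.36 and 7.85 in TBI 1 to 4. TBI 3 lay below all controls. Ly6g, a surface marker of mature neutrophils, was at 1.16 ± 0.50 (SE), the collagenase Mmp8 at 1.18 ± 0.55, Chil3 at 1.10 ± 0.52 and the iron-binding protein Lcn2 at 0.97 ± 0.52. Without TBI 1, Mmp8 was at 0.62, Chil3 at 0.65 and Lcn2 at 0.57. The granule proteases Elane and Prtn3 were at 0.94 ± 0.44 and 0.93 ± 0.41, and Fcnb at 1.12 ± 0.53. In edgeR 0 members of either neutrophil list passed when adjusted over the list alone, 1 late gene (Ly6g) and 0 precursor genes had an unadjusted p under 0.05, and DESeq2 called 0.

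Interferon-induced genes rose as a list (median log2 fold change 0.59, 25 of 26 members higher, camera adjusted p = 2.90e-07; adjusted p = 0.653 with an estimated correlation). In edgeR 0 members passed when adjusted over the list alone (3 at an unadjusted p under 0.05, 0 in DESeq2). The list mean was 6.09 log2 CPM in TBI 1 and 5.11, 4.32 and 4.57 in TBI 2 to 4, against 4.54, 4.38 and 4.57 in the controls. Without TBI 1 the median was 0.17 and the adjusted p 0.0729 in camera. With the late neutrophil list mean as a covariate, chosen after seeing the data, the interferon median was 0.0844 (adjusted p = 0.293). Zbp1, Oas2 and Ifi44 were at 1.45 ± 0.59, 1.41 ± 0.56 and 1.29 ± 0.50 (SE), and at 0.66, 0.75 and 0.66 without TBI 1. The acute phase and STAT3 response list rose at a median of 0.43 with 10 of 14 members higher (camera adjusted p = 4.13e-04; adjusted p = 0.614 with an estimated correlation). Its call ended without TBI 1 (adjusted p = 0.0729), and the median was 0.66 without control 1 and 0.25 without TBI 4. It also ended with the same neutrophil covariate (median 0.0396, adjusted p = 0.207); Lcn2 and Cd177 stand on both lists. Fgl2, a fibrinogen-like protein of immune cells (ENSMUSG00000039899, chromosome 5, 21372642 to 21378374, plus strand), was its only member past the threshold when adjusted over the list alone, at 0.67 ± 0.13 and from 26.3 ± 1.96 CPM (SD, n = 3) to 41.9 ± 4.69 CPM (SD, n = 4). Lrg1 was at 0.74 ± 0.22 and haptoglobin (Hp) at 0.93 ± 0.36. The 4 lower members were Socs3 (−0.12 ± 0.17), Steap4 (−0.10 ± 0.11), Pim1 (−0.09 ± 0.21) and Bcl3 (−0.08 ± 0.18). Stat3 itself was at 0.11 ± 0.13. These 5 genes were singled out after their values were seen, and a STAT3 response as such was not tested. The megakaryocyte and platelet list rose at 0.39 with 17 of 17 members higher (camera adjusted p = 2.82e-04; adjusted p = 0.686 with an estimated correlation), and 0 passed in edgeR when adjusted over the list alone (0 at an unadjusted p under 0.05, 0 in DESeq2). The median was 0.81 without control 1, 0.24 without control 2 and 0.23 without TBI 2, and the call ended without control 3 (median 0.22, adjusted p = 0.1) and with the neutrophil covariate (0.11, adjusted p = 0.407). Ppbp was at 0.58 ± 0.39, Tubb1 at 0.45 ± 0.30 and Vwf at 0.33 ± 0.19. Each of these 3 genes was highest without control 1, at 1.18, 0.85 and 0.55. Ppbp was at 0.36 without control 2 or control 3, and Tubb1 at 0.29 without control 2 and 0.30 without control 3.

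**Figure D2:**
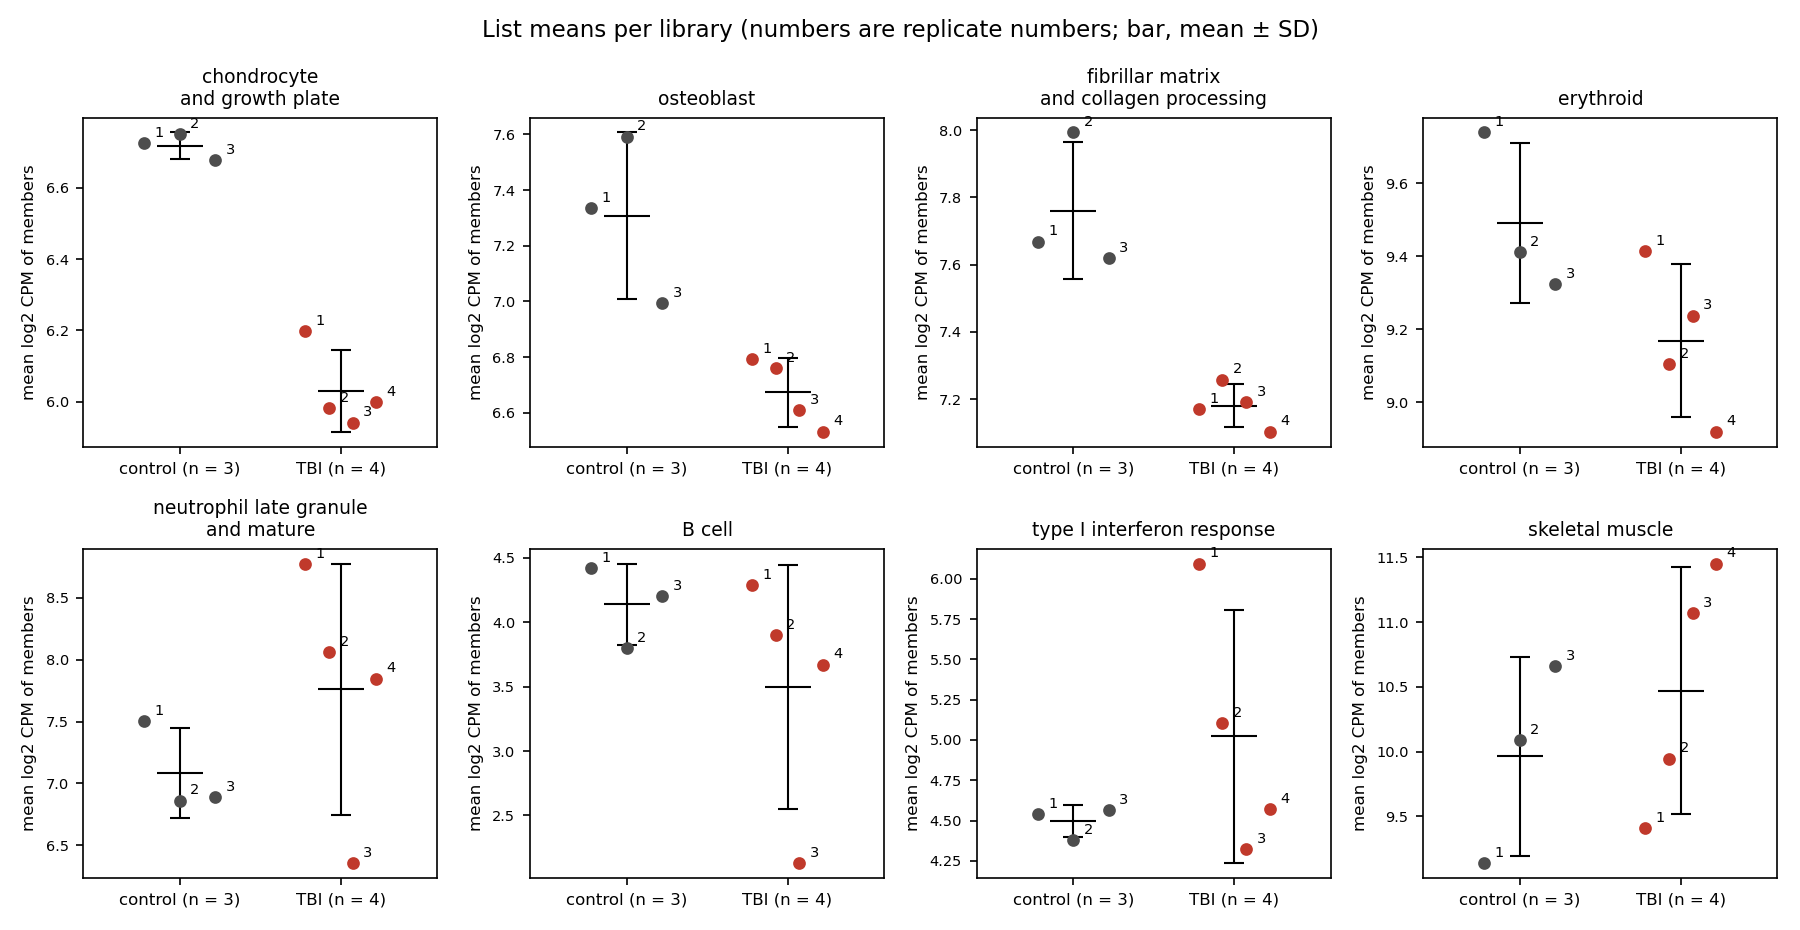
Mean log2 CPM (vertical axis, a separate scale in each panel) of the members of 8 gene lists in each of the 3 control and 4 TBI libraries; points are libraries with their replicate number, and bars are the group mean ± SD. The chondrocyte, osteoblast and fibrillar matrix lists separate the groups, and the late neutrophil, B-cell, interferon and muscle lists vary more between TBI libraries than between groups.

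Skeletal muscle mRNA made up a large and uneven part of the libraries. The muscle list took 2.67%, 4.94% and 8.07% of counts in controls 1 to 3 and 3.23%, 4.95%, 10.6% and 13% in TBI 1 to 4 (exact permutation p = 0.343). The list rose in camera with the preset correlation (median log2 fold change 0.71, 25 of 26 members higher, adjusted p = 3.11e-04; adjusted p = 0.686 with an estimated correlation), but without TBI 3 and TBI 4 together, chosen after seeing the data, it was called lower (median −0.40, adjusted p = 0.0142). The call ended without control 1 (median 0.37, adjusted p = 0.481), TBI 3 (0.51, adjusted p = 0.065) or TBI 4 (0.30, adjusted p = 0.289), and the median was 1.16 without control 3. Acta1, the actin of skeletal muscle, was at 0.59 ± 0.59 (SE) and −0.44 without TBI 3 and TBI 4, and Actn3, Ckm and Myoz1 at 0.99 ± 0.72, 0.89 ± 0.65 and 0.90 ± 0.62. These 4 genes moved by over 1.5 times when control 1, control 3 or TBI 4 was left out: Acta1 to 0.25, 1.08 and 0.25, Actn3 to 0.62, 1.66 and 0.52, Ckm to 0.54, 1.42 and 0.43, and Myoz1 to 0.56, 1.36 and 0.51, in that order of libraries.

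Energy metabolism and fat genes moved together with the muscle signal. The nuclear respiratory chain list rose at a median log2 fold change of 0.33 with 26 of 26 members higher (camera adjusted p = 9.21e-05; adjusted p = 0.686 with an estimated correlation). The mitochondrially encoded list rose at 0.38 with 13 of 13 higher (camera adjusted p = 0.00872; adjusted p = 0.686 with an estimated correlation). The hypoxia and glycolysis list rose at 0.39 with 15 of 19 higher (camera adjusted p = 0.00627; adjusted p = 0.653 with an estimated correlation). The adipocyte list rose at 0.67 with 18 of 18 higher (camera adjusted p = 2.90e-07; adjusted p = 0.614 with an estimated correlation). In edgeR 0 members of these 4 lists or of the muscle list passed when adjusted over the list alone, and DESeq2 called 0. At an unadjusted p under 0.05 there were 4 adipocyte, 2 glycolysis, 1 mitochondrially encoded, 0 respiratory chain and 0 muscle genes. Over the 7 libraries, the muscle list mean correlated with the nuclear respiratory chain list mean at Pearson's r = 0.99 (exact permutation p = 5.95e-04, adjusted p = 0.00268 over 9 relations). Spearman's rho was 0.96 (exact permutation p = 0.00278), and r was 0.97 without TBI 3 and TBI 4, the libraries farthest from the median of the muscle list. For glycolysis r was 0.99 (exact permutation p = 3.97e-04, adjusted p = 0.00268; rho 0.96, exact permutation p = 0.00278; r 0.98 without TBI 3 and TBI 4). For the mitochondrially encoded list r was 0.95 (exact permutation p = 0.00377, adjusted p = 0.0113; rho 0.93, exact permutation p = 0.00675; r 0.91 without those 2). For the adipocyte list r was 0.88 (exact permutation p = 0.00814, adjusted p = 0.0183; rho 0.93, exact permutation p = 0.00675; r 0.90 without those 2). None of the other 5 relations (erythroid, osteoblast, chondrocyte, late neutrophil and interferon lists) passed an adjusted p of 0.05. The erythroid list came nearest, at r = −0.78 (exact permutation p = 0.0319, adjusted p = 0.0575). For the osteoblast list r was −0.55 over all libraries (exact permutation p = 0.203) and −0.0351 without TBI 3 and TBI 4. Within the 4 TBI libraries it was −0.99, where the interferon list had r = −0.91. These values within the TBI group were not tested.

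Without TBI 3 and TBI 4 the medians of these lists were −0.13 for the nuclear respiratory chain (adjusted p = 0.176), −0.36 for the mitochondrially encoded genes (0.0429, called lower), −0.11 for glycolysis (0.636) and −0.0072 for adipocytes (0.872). With the muscle list mean as a covariate the calls ended for the respiratory chain (median 0.0491, adjusted p = 0.318), glycolysis (0.10, adjusted p = 0.115) and mitochondrially encoded lists (−0.0524, adjusted p = 0.748), while the adipocyte list kept its call (0.41, adjusted p = 0.00539). With the erythroid list mean as a covariate the adipocyte call ended (0.41, adjusted p = 0.145), and 4 medians turned negative. The muscle (−0.40, adjusted p = 3.06e-05) and respiratory chain lists (−0.17, adjusted p = 0.00718) were called lower there, the glycolysis (−0.12, adjusted p = 0.402) and mitochondrially encoded lists (−0.24, adjusted p = 0.161) were not. Leaving out single libraries also ended calls. The mitochondrially encoded list was no longer called without control 1 (0.12, adjusted p = 0.477), TBI 3 (0.10, adjusted p = 0.463) or TBI 4 (0.21, adjusted p = 0.151). The same held for the respiratory chain list without control 1 (0.17, adjusted p = 0.16) or TBI 4 (0.15, adjusted p = 0.0537), and for the glycolysis list without control 1 (0.33, adjusted p = 0.211), TBI 3 (0.34, adjusted p = 0.0689) or TBI 4 (0.24, adjusted p = 0.147). The adipocyte median was 0.38 without TBI 3, the mitochondrially encoded median 0.58 without TBI 1 and the respiratory chain median 0.49 without control 3. Among adipocyte genes, the hormone gene Adipoq was at 0.60 ± 0.24 (SE), Cebpa at 0.50 ± 0.17 and the hormone-sensitive lipase Lipe at 0.76 ± 0.31 (0.42 without TBI 3). Sdha, Cox5b and Cox7c were at 0.51 ± 0.33, 0.34 ± 0.21 and 0.32 ± 0.21, and at 0.28, 0.22 and 0.19 without TBI 4; Cox5b was at 0.22 without control 1. The mitochondrial genes mt-Atp8, mt-Nd2 and mt-Nd3 were at 1.25 ± 0.35, 0.55 ± 0.44 and 0.55 ± 0.38. Of these, mt-Nd2 was at 0.33 without control 1 or TBI 3 and 0.32 without TBI 4, and mt-Nd3 at 0.32 without control 1 and 0.22 without TBI 3. On the glycolysis list, Car9 was at 1.10 ± 0.30 and Pfkfb3 at 1.41 ± 0.62 (0.52 without TBI 3), while P4ha1, which also helps to make collagen, was at −0.26 ± 0.11.

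**Figure D3:**
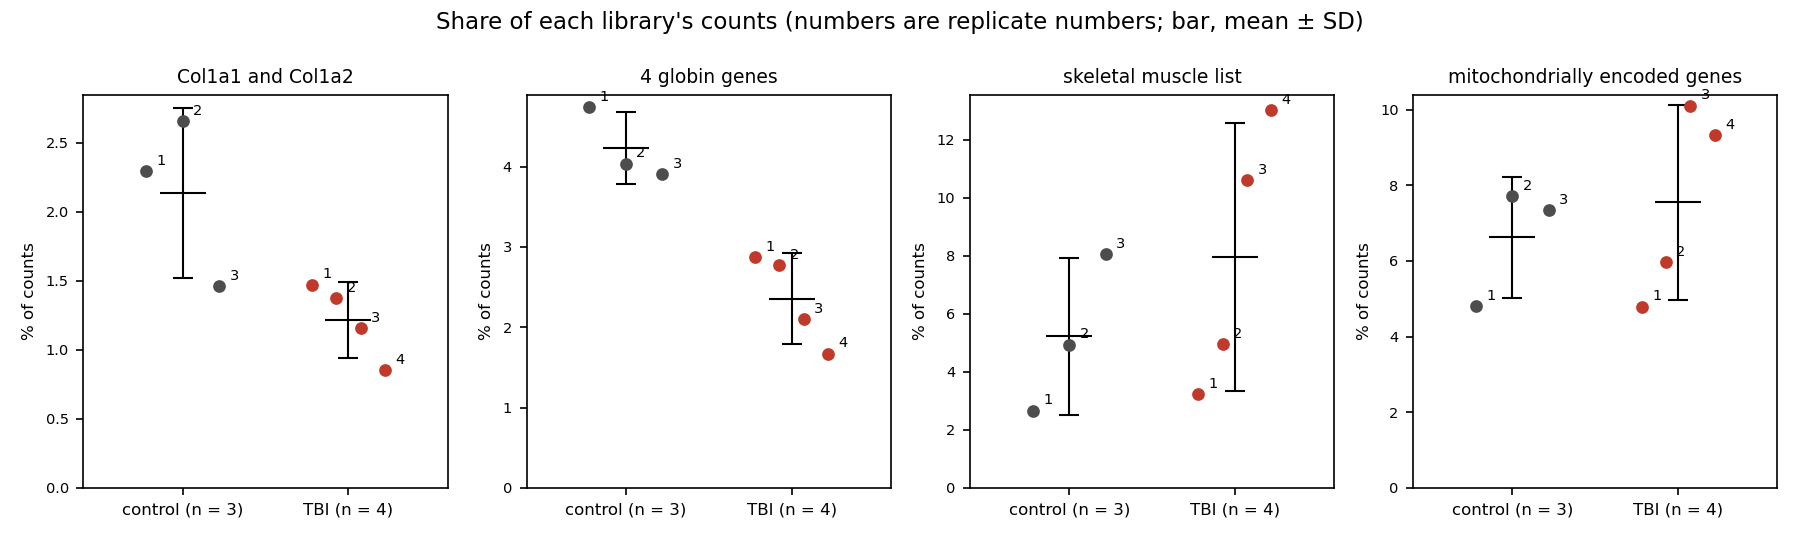
Percent of all counts (vertical axis, from 0) taken by Col1a1 and Col1a2, the 4 globin genes, the skeletal muscle list and the mitochondrially encoded genes in each of the 3 control and 4 TBI libraries; points carry replicate numbers and bars are mean ± SD. All TBI libraries lie below all controls in globins, whereas the muscle share reaches 13% in TBI 4 and overlaps between groups.

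The glucocorticoid and the cytokine and NF-kB lists were not called with the preset correlation. Their difference from the interferon and acute phase lists above was not tested, and with an estimated correlation none of them was called. The glucocorticoid response list had a median log2 fold change of 0.20 (camera adjusted p = 0.158), and Fkbp5, a widely used glucocorticoid target, was at 0.69 ± 0.30 (SE) and 0.44 without TBI 1. The inflammatory cytokine and NF-kB list stood at 0.06 (adjusted p = 0.637), monocytes and macrophages at 0.09 (0.361), immediate early and heat shock genes at −0.06 (0.361), adrenergic and neuropeptide signalling at −0.10 (0.425) and Schwann cells and nerve at −0.12 (0.418), each adjusted p from camera. Medians were 0.22 for T and NK cells (0.443), 0.04 for dendritic cells (0.443), −0.18 for plasma cells (0.69), −0.00 for eosinophils, basophils and mast cells (0.718), 0.04 for MHC class II (0.724), 0.02 for stem and progenitor cells (0.471), 0.04 for endothelium (0.448) and 0.02 for marrow stroma (0.724). The cell cycle list was at −0.08 (0.131), the unfolded protein response at −0.01 (0.62), cytosolic ribosomal proteins at 0.03 (0.637) and the circadian clock at −0.02 (0.819). For 7 of these lists (dendritic, plasma cell, eosinophil, MHC class II, marrow stromal, unfolded protein response and clock) the median, mean and test differed in sign. Pdgfra on the marrow stromal list was the only member of these lists past the threshold when adjusted over the list alone, at −0.52 ± 0.10; it was singled out after its value was seen.

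In single genes, edgeR called 0 of 17144 at an adjusted p under 0.05, and the smallest adjusted p was 0.423. At an unadjusted p under 0.05 there were 1259 genes, 407 higher and 852 lower, where 857 would be expected by chance on average. Other splits of the 7 libraries into 3 and 4 gave 109 to 4783 such genes, so the excess over 857 does not exclude chance. DESeq2 called 114 genes, 10 higher and 104 lower, all of them at an unadjusted edgeR p under 0.05, and 27 of them on the 5 skeletal lists. With single libraries left out, a setting of DESeq2 chosen after seeing the data, its count was 4 without control 2, 57 without control 3, 69 without TBI 1, 75 without TBI 2, 207 without TBI 3 and 33 without TBI 4. The genes with the smallest p among lower estimates were Thbs3 (−0.80 ± 0.10, SE), a thrombospondin of the skeletal matrix, Gxylt2 (−0.81 ± 0.12), Col9a2, Col24a1 (−0.82 ± 0.13), a fibrillar collagen of developing bone, and Cd109 (−0.81 ± 0.13). Among higher estimates they were Fgl2, the transcriptional regulator Cited2 (0.51 ± 0.10), Alas1 (0.80 ± 0.17), the housekeeping counterpart of Alas2, Fmo5 (0.64 ± 0.14) and Mtm1 (0.73 ± 0.16). The groups did not overlap in CPM for 1378 genes, 8.04% of those tested, where chance gives 5.71% on average. How far this share varies between splits was not tested, so the excess does not exclude chance.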

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

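The tests of skeletal share, added RNA, marrow share, muscle carry-over and muscle gene ratios, and the counts of splits for edgeR genes and for the skeletal lists, were chosen after the results were seen. Within the 4 TBI libraries, 130 values were examined for a library standing far from the other 3, and 4 were, fewer than the 6.5 that chance gives at about 1 in 20. Atp6v0d2 was at 45.8 CPM in TBI 1 against 26.9 to 28.7 in the others. Col9a2 was at 126.4 CPM in TBI 1 against 96.6 to 100 in the others, and Ifi44 at 14.1 CPM in TBI 1 against 3.63 to 5.36. Col1a1 was at 4946 CPM in TBI 4 against 6534 to 6733.

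The lower bone, cartilage and tendon lists were weighed against added RNA from muscle or other tissue, a smaller share of skeletal tissue, and a GC or length bias. For added RNA, the stem-cell and cell-cycle lists were taken as the reference after the results were seen. The difference from them is therefore no independent test. Added RNA would lower marrow genes alike, but set against the stem-cell and cell-cycle lists of the same library, which changed by −0.0278, the skeletal lists differed by −0.62 (log2, TBI minus control; 0.44 ± 0.22 in controls and −0.18 ± 0.11 after TBI, SD, exact permutation p = 0.0571), without overlap. Of the other marrow lists, the erythroid (−0.26), osteoclast (−0.27), B-cell precursor (−0.42) and B-cell lists (−0.56) also had lower medians and the late neutrophil list a higher one (0.97), so the marrow lists did not fall alike, but within the 4 TBI libraries the osteoblast mean was lower where the muscle mean was higher (r = −0.99), and added RNA is argued against as the whole cause only. After a loess trend on GC content and transcript length was removed, the median of the 84 skeletal genes was −0.67, against −0.66 before. A smaller share of skeletal tissue in the crushed femurs remains open. The medians of the 5 lists spanned only 0.10, as 1 tissue share would give, and a permutation of genes over lists gave p = 0.493. These lists were grouped because they were lower, and the osteoclast list (−0.27) was left out. A narrow span was thus partly built in, and a high p does not show equal shifts, so neither value decides. A smaller share could come from dissection or from an effect of the injury on bone cells, which was not tested apart from it.

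The count of lists called with an estimated correlation was 1 in the real split and 0 in the 34 others (1 of 35 splits as large). This is the smallest share that the splits allow. The count rests on the chondrocyte list alone, at an adjusted p of 0.049 in limma's camera. It is 1 of 5 such counts, with no allowance for their number, so it does not exclude chance. The directional fry test called all 5 skeletal lists at an unadjusted p under 0.05 in the real split and at most 3 in another (1 of 35), but these lists were chosen because they were lower in the real split, so this says nothing about chance. Chance can also not be excluded for the counts of lists with the preset correlation and of DESeq2 genes. With the preset correlation, 18 of the 35 splits called at least the 21 lists of the real split, with up to 29 in another; DESeq2 reached the real 114 genes in 6 of 35, with up to 2849 in another. The edgeR count says nothing about chance, since a real count of 0 is reached in 35 of 35 splits by definition, with up to 1326 genes. The splits with most edgeR calls set control 3, TBI 3 and TBI 4 against the rest (1326 genes) and control 1, TBI 1 and TBI 2 against the rest (1136 genes). The first of these groups holds the 3 libraries with the highest muscle shares, so a structure of the samples other than injury carries the largest differences.

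The higher neutrophil lists were weighed against a larger share of marrow and uneven muscle carry-over. More marrow would raise B-cell genes too, but the neutrophil minus B-cell difference of the list means rose by 1.35 (log2; 2.21 ± 0.245 in controls and 3.55 ± 0.117 after TBI, SD, exact permutation p = 0.0571), without overlap. The B-cell list was taken for this after it was seen to be lower, the neutrophil mean of TBI 3 (5.66) lay below the controls (6.13 to 6.78), and set against the erythroid list the rise was 1.03 with overlapping groups (exact permutation p = 0.229). With the muscle list as a covariate the late neutrophil median was 1.18 (quartiles 1.06 and 1.27), against 0.97 without. An effect of the injury on neutrophils was not tested apart from these, and the neutrophil lists alone overlapped between the groups (exact permutation p = 0.343).

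The uneven muscle signal was weighed against muscle left attached to some femurs. Attached tissue would bring its mRNAs in fixed ratios, and a muscle gene varied against its list mean by a median SD of 0.152 (log2) over the 7 libraries, while the list mean itself varied by an SD of 0.85. Muscle carry-over is therefore a candidate source of the muscle, respiratory chain and glycolysis values. A change of muscle after injury was not tested apart from it, and the list means overlapped between groups (exact permutation p = 0.457).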

How the results depend on the processing

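The DESeq2 runs with a library left out or a covariate, the neutrophil covariate, the newer quasi-likelihood fit and the runs without both TBI libraries of highest muscle share (TBI 3 and TBI 4) were chosen after seeing the data; the other settings were fixed beforehand. In edgeR and limma-voom, 0 genes passed an adjusted p of 0.05 in the settings run, each library left out and a minimum fold of 1.5 included. Apart from the minimum fold, 592 to 2764 genes had an unadjusted p under 0.05, and the smallest adjusted p ranged from 0.0599 (muscle covariate) to 0.987 (without control 2). A threshold of 0.1 was applied with no covariate, block or weights and gave 0 genes, whereas the muscle covariate, the replicate block (0.0784) and voom with quality weights (0.0851) had a smallest adjusted p under 0.1. DESeq2 called 114 genes (10 higher, 104 lower), and the cause of its difference from edgeR was not tested. On the simulated counts it made 45 false calls, against 11 in edgeR, so some of the 114 may be false. Leaving out 1 library moved the DESeq2 count between 4 and 207 genes, 0 to 148 higher and 4 to 107 lower. Of the 114 genes, between 4 (without control 2) and 64 (without control 1) were called again in those runs. Without TBI 3 and TBI 4 the count was 430 (361 higher, 69 lower), with 53 of the 114 among them. With the muscle covariate it was 726 (359 higher, 367 lower), with 108 of the 114 among them. All 114 kept their direction in these 9 runs. Over all libraries these genes had separated groups (104 with all TBI below all control, 10 with all TBI above). Leaving out libraries could therefore hardly turn a direction, so the agreement is no test of these genes. Of 354 comparisons of the 21 called lists with an alternative, 344 kept camera's direction and 272 the call as well. The adipocyte median, −0.0072 without TBI 3 and TBI 4, changed sign although camera's direction did not. In addition, the 5 skeletal lists and the Wnt, erythroid and late neutrophil lists kept their calls under every camera setting with the preset correlation. The erythroid and late neutrophil covariates were not applied to their own lists. Camera with an estimated correlation and fry each called 1 list (0 higher, 1 lower), and both allow for the correlation among members. With the neutrophil covariate 22 lists were called (6 higher, 16 lower), and the interferon, acute phase, megakaryocyte and neutrophil precursor calls ended. Leaving out 1 library gave 16 to 22 lists, 6 (without control 1) to 11 higher and 10 to 14 lower. With the replicate block, 0 genes and 23 lists (11 higher, 12 lower) passed, 20 of the 21 main calls among them; the mitochondrially encoded list did not pass (adjusted p = 0.119). The labels do not say whether the numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.549, −0.0277 and 0.322, and control 2 and control 3 correlated best with another number. So few correlations cannot exclude a pairing or a shared order of processing. The muscle share of counts rose with the replicate number in both groups.

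Directions turned mainly in muscle and energy genes. With the erythroid covariate the list medians were −0.40 for muscle, −0.12 for glycolysis, −0.17 for the nuclear respiratory chain, −0.24 for the mitochondrially encoded genes and 0.011 for osteoclasts, and the genes Acta1 −0.52, Actn3 −0.30, Ckm −0.37, Cox5b −0.0699, Cox7c −0.09, mt-Nd2 −0.13, Myoz1 −0.25, Sdha −0.0938 and Dmp1 0.26. Without TBI 3 and TBI 4 the lists were −0.40 for muscle, −0.11 for glycolysis, −0.13 for the respiratory chain and −0.36 for the mitochondrially encoded genes, and the genes Acta1 −0.44, Actn3 −0.54, Ckm −0.40, Cox7c −0.0186, mt-Nd2 −0.28, mt-Nd3 −0.18, Myoz1 −0.40 and Sdha −0.11. With the muscle covariate the mitochondrially encoded list was −0.0524, and the respiratory chain (0.0491) and glycolysis (0.10) calls ended. The cause of these reversals was not tested, apart from the muscle share that the left-out libraries carry. The 83 named genes kept direction in 1631 of 1648 comparisons. At this depth and group size, simulated 1.5-fold changes were recovered in 0 of 67 genes by edgeR.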

Other observations

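The genes named here and the test of late red-cell genes were chosen only after the results were seen. Several genes outside the fixed lists passed in DESeq2, and their log2 fold changes here are edgeR's. Orm1, which encodes the acute phase protein orosomucoid, had a log2 fold change of 1.32 ± 0.30 (SE, DESeq2 adjusted p = 0.0097) and went from 3.64 ± 1.42 CPM (SD, n = 3) to 9.18 ± 2.29 CPM (SD, n = 4), and C3, the central complement protein, was at 0.88 ± 0.21 (DESeq2 adjusted p = 0.0231). Bpgm, the red-cell enzyme that makes the regulator of haemoglobin's oxygen affinity, was at −0.79 ± 0.15 (DESeq2 adjusted p = 1.12e-04), and Slc25a39, a mitochondrial carrier, at −0.53 ± 0.14 (DESeq2 adjusted p = 0.0287). In edgeR the adjusted p of Orm1, C3 and Bpgm was 0.423 and that of Slc25a39 0.443.

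The mRNAs of Jchain and Ighm were highest in TBI 1 and also lay above every control in TBI 2. The mean of the plasma cell list, which holds Jchain, was also highest in TBI 1, at 4.03 log2 CPM. That list was not called (median log2 fold change −0.175, camera adjusted p = 0.69). Jchain, which joins secreted IgM and IgA, was at 189.2 CPM in TBI 1 and 67.3, 32.1 and 23.1 in TBI 2 to 4, against 22.8 to 25.7 in controls. Ighm was at 1587, 649.4, 272.7 and 261.1 CPM in TBI 1 to 4, against 265.6 to 380.9 in controls. TBI 1 also had the highest interferon and late neutrophil list means.

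A hypothesis formed after seeing the globin values is that the injured femurs held fewer late red cells, or less blood, while early erythroid cells were less affected. The 4 globin genes differed by −0.61 (log2, TBI minus control) from the other erythroid genes of the same library, without overlap (4.16 ± 0.177 in controls, 3.55 ± 0.17 after TBI, SD, exact permutation p = 0.0571). The test, chosen after the globin values were seen, used 8 late red-cell genes without globins or Bpgm against 10 early erythroid genes, and late minus early differed by −0.21 (0.868 ± 0.12 in controls and 0.655 ± 0.142 after TBI, SD, exact permutation p = 0.114). The direction was the predicted one, but the predicted separation of the groups was not met: TBI 4 at 0.839 lay above control 1 at 0.74. With 7 libraries the difference may or may not be real, and fewer late red cells cannot be told apart from a lower level of globin mRNA per cell.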
